A study of Danio rerio with 8 samples.

How the data were processed

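RNA of zebrafish kidney and intestine was compared between fish homozygous for a rag1 mutant allele and their heterozygous siblings on 8 Agilent two-colour arrays. Each array carried mutant and heterozygote cRNA of 1 tissue in opposite dyes. Per the labels, each tissue had 2 biological replicates, and each replicate was hybridised as a pair of arrays with the dyes exchanged. Whether a replicate was 1 fish or several, and whether replicate 1 of kidney and of intestine came from the same fish, is not given in the sources used here.

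Per the labels, the authors extracted total RNA with Trizol and converted 1 microgram of it into Cy3 or Cy5 cRNA with an Agilent linear amplification kit. Per the file headers, the arrays were scanned and read with Agilent Feature Extraction 8.5.1.1, and each deposited array file holds mean foreground and median local background intensity for both dyes, with a flag for spots well above background, which that software sets at 2.6 SDs over background. The files of 3 arrays hold rounded intensities and gene names altered as by a spreadsheet. For those arrays, probes were named from the remaining files.

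The deposited value table holds log2 ratios. Set against the scanner ratios of the same arrays, its values were log2 of mutant over heterozygote on every array, already turned for the exchanged dyes, minus each probe's own median over the 8 arrays. Of 21495 probes, 98.8% had a median within 0.05 of 0 over its columns. Correlations across probes with the scanner software's processed ratios ran from 0.743 to 0.935 before those ratios were centred by probe, and from 0.965 to 0.986 after centring, with slopes of 0.874 to 1.03. The medians of its columns were 0.00666, 0.00542, -0.0270 and 0.0364 for the kidney arrays and 0.0105, -0.0176, -0.0471 and 0.0285 for the intestine arrays. After this comparison neither scale, centring nor direction stays unknown, but the method that made the table is not given in the sources used here. Because each probe was centred, the table was used only for the difference between tissues.

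Each array held 22575 spots, of which 21495 were gene probes, 918 positive controls and 162 negative controls. Background was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, and ratios were normalised within each array by loess with control spots at weight 0. Control spots and spots that the scanner software marked as outliers were then left out. Ratios were turned to mutant over heterozygote, and the arrays of a dye-exchange pair were averaged, which gave 4 replicate values. A linear model with 1 mean per tissue was fitted with limma (lmFit and eBayes), with 2 residual degrees of freedom and 1.74 prior degrees of freedom. Probes were tested in a tissue when at least 1 genotype was well above background on all 4 of its arrays. This left 10482 probes (8582 genes) in kidney, 8086 (6609 genes) in intestine and 7719 (6303 genes) for the tissue difference, coded as kidney minus intestine. Adjusted p values follow Benjamini and Hochberg, with a threshold of 0.05, and all p values are from limma. Where 1 genotype was not well above background on any array of a tissue, the ratio is a lower bound, given as at least N-fold, from channel intensities normalised by loess and Aquantile, and no fold is given where the floor exceeds the other genotype, as for rag1 and rag2 in intestine.

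Probes were named through the accession in the array file where the reference tables for assembly GRCz12tu hold it. The assembly was used only for names. An accession named 7323 probes, a current symbol 657 and an older symbol 2353, and 11162 kept the name in the array file. A gene symbol was held by 10066 probes, for 7022 symbols. A few older names that lead to a different gene were excluded by hand after the names had been inspected, among them vg1, which the array file describes as vitellogenin 1. Several probes of a gene were represented by the brightest one over all 8 arrays, and the others were checked for disagreement.

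The gene lists, the models, the rule for named genes and most alternative settings were fixed before the data were examined. The rule names, per tissue, rag1 and rag2 and the 12 highest and 12 lowest log2 ratios among genes past the threshold with the same sign on all 4 arrays. For the tissue difference it names 6 in each direction, and for each list up to 4 members with the largest ratios, of which not all are reported here. Places left open by the threshold were filled with the largest ratios among tested genes, which did not pass. Probes for nephrosin, IgM heavy chain, T cell receptor beta and a haptoglobin-like transcript fall outside the rule and were chosen after their values were seen.

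The 25 lists were B cell, T cell, recombination and lymphoid progenitor, cytotoxic and NK-like, complement, coagulation, hepatocyte and plasma protein, acute phase, exocrine pancreas, neutrophil, macrophage, erythroid, thrombocyte, interferon response, MHC class II, MHC class I and immunoproteasome, inflammatory cytokine and innate receptor, enterocyte, secretory gut cell, nephron, cell cycle, stress and immediate early, muscle, vitellogenin and oocyte, and ribosomal protein. Lists with at least 5 tested genes were tested with camera (limma), which compares a list's genes with all other tested genes, at a preset correlation of 0.01. Adjustment was over lists. Each list was also tested with an estimated correlation and with fry, and list members were also adjusted over the list alone. With an estimated correlation, camera rests on the 2 residual degrees of freedom, so a lost call need not reflect correlated genes. The kidney interferon list had an estimated correlation of -0.03, below the preset value. Its unadjusted camera p still rose from 6.83e-10 to 0.0220.

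The arrays fell into 2 scan batches of 4 arrays. Replicate 1 of both tissues was in the first batch and replicate 2 in the second, so that values per replicate are also values within a batch, and a scan batch block is also a block on the replicate number. Alternatives covered background correction, normalisation, the filter on dim probes, the eBayes prior, arrays kept apart with the replicate as a random block (statmod 1.5.0) with and without a dye term, 1 dye orientation at a time, the scanner software's processed signals, the value table, a scan batch block, and leaving out each replicate. Lists without genes that another list holds, and the alternatives for the lists of the tissue difference, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

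The model was tested on simulated data with the number of replicates of the real arrays and a spread drawn from the fitted prior. For a comparison of 10482 probes in kidney, 2, 28, 44 and 49 of 50 probes changed by log2 0.5, 1, 2 and 4 were called, with 7 false calls among 10282 unchanged probes. For the tissue difference over 7719 probes, 1, 18, 41 and 48 of 50 were called at those sizes, with 10 false calls among 7499. Estimated ratios of changed probes had a slope on the simulated ones of 0.783 in kidney and 0.789 in the difference. Sizes were thus understated in the simulation. With no simulated change, no call was made in any of the 3 comparisons. In intestine, over 8086 probes, 0 of 20 probes changed by log2 0.4 were called one by one. As a list these 20 genes were found by camera in intestine and in the tissue difference, and an unshifted list of 20 genes was not. The simulated genes varied independently, whereas correlations estimated in the real lists reached 0.90 (ribosomal protein). The simulation therefore cannot show how camera at the preset correlation behaves with such correlated lists. Simulated replicates varied independently too, whereas real deviations from the tissue mean correlated at 0.434 between tissues for the same replicate number. In simulated kidney 512 of 10282 unchanged probes had an unadjusted limma p under 0.05, and in real kidney 300 of 10482 probes. The counts of recovered probes may therefore not hold for the real arrays. The number of arrays limits the precision of every value.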

Results

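Gene expression was measured in kidney and intestine of zebrafish homozygous for a rag1 mutant allele and of their heterozygous siblings. Rag1 is 1 of the proteins that cut DNA to assemble B and T cell receptor genes, the kidney is the main blood-forming organ of adult fish, and the intestine is a tissue in contact with microbes. Each tissue had 2 biological replicates, each measured on a pair of arrays with exchanged dyes. Median foreground intensity per array was 66.4 to 107 in Cy5 and 84.3 to 124 in Cy3, over a background of 55 to 57 and 41 to 43. Signal over background in Cy5 was lowest for replicate 1 of intestine (1.21 on both arrays) and highest for replicate 2 of kidney (1.77 and 1.91). Between 36.4% and 58.6% of probes were well above background in Cy5 and between 56.3% and 67.9% in Cy3. Values are log2 ratios of mutant over heterozygote, with the SE of the fit and n = 2 replicates per tissue. Across genes, which are not independent replicates, the arrays of a dye-exchange pair correlated at 0.571 to 0.848, but the replicates of a tissue at 0.0179 in kidney and 0.0266 in intestine. Replicates of different tissues scanned in the same batch correlated at 0.292 and 0.327.

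The targeted gene itself was near background. The rag1 probe had a log2 ratio of 0.13 (SE 0.07; 0.03 and 0.22 in replicates 1 and 2) in kidney, and it was not tested in either tissue, because neither genotype was well above background on all 4 arrays of a tissue (mutant RNA on 3 kidney and 0 intestine arrays, heterozygote RNA on 3 and 1). Its kidney ratio (rag1 level check) was -0.04 with only the arrays carrying the mutant in Cy5, 0.29 with only those carrying it in Cy3, 0.35 with offset 0 and 0.36 with the scanner software's processed signals. In intestine mutant RNA was not well above background on any array, and no bound could be given, since the lowest signal well above background exceeded the heterozygote signal. The allele is not given in the labels, so a lower level at this probe is not required. The rag2 probe, for the partner of Rag1 in receptor gene assembly, had a ratio of 0.00 in kidney, was likewise without a bound in intestine and was not tested either.

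The first comparison asks which transcripts differ in mutant kidney, where blood cells form. Probes for IgM heavy chain, the antibody chain made by B cells, had low ratios in kidney: -1.74 (SE 0.18; -2.01 and -1.47), or 3.34-fold lower, and -1.88 (SE 0.29; -2.22 and -1.54), or 3.68-fold lower. A probe for nephrosin, an astacin-type protease of fish blood-forming tissue, had a ratio of -3.14 (SE 0.22; -2.73 and -3.54), measured on 3 of 4 kidney arrays. Its replicate 2 value came from 1 array, with the mutant in Cy5. The size depended on the processing: -2.83 with median centring without loess, -4.30 with offset 0 and -5.33 with the processed signals. With only the mutant in Cy3 it was -2.645, from 1 array of replicate 1 alone. Probes assigned to npsn, the neutrophil gene of that name, had ratios of 0.12 and -0.11. These probes were chosen after their values were seen. None passed the limma test (adjusted p = 0.893 and 1.00 for the IgM probes and 0.609 for the nephrosin probe), but with arrays kept apart and the replicate as a random block they had adjusted p = 0.00261, 0.0157 and 5.93e-04. That fit counts the arrays of a dye-exchange pair toward the degrees of freedom, although kidney had 2 biological replicates, so its adjusted p can be too low. Other lymphocyte transcripts had measured ratios nearer 0, in both directions, but some of their probes were dim. A T cell receptor beta transcript had a ratio of -0.22 (-0.68 and 0.24), trac, the receptor alpha constant gene, -0.15 (-0.66 and 0.36), and the T cell kinase gene lck -0.27 (-0.59 and 0.06). Of the T cell list 6 of 7 tested genes lay below 0, but only 1 in both replicates, and runx3 had 0.16 (0.15 and 0.17). The B cell adaptor gene blnk had -0.31 (-0.28 and -0.33), but 2 of 3 tested B cell genes lay above 0, among them syk at 0.08. Mean log2 intensity was 6.13 for syk, 6.62 for blnk and 6.69 for T cell receptor beta. It was 7.61 and 8.55 for the IgM probes, and 7.08, 7.47 and 7.49 for lck, runx3 and trac. The background offset draws ratios of dim probes toward 0, so their sizes cannot be set against those of IgM. Over the alternative settings blnk ran from -0.55 to -0.26 and syk from -0.03 to 0.25.

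Erythroid genes, which serve haemoglobin and the red cell membrane, fell as a group in mutant kidney relative to other genes, with 21 of 23 below 0 (14 in both replicates) and a median of -0.33 (-0.38 in replicate 1 and -0.26 in replicate 2). The camera adjusted p was 1.83e-14, and adjusted p = 0.357 with an estimated correlation. Members with the lowest ratios were the alpha globin gene hbaa1 (-1.01), the carbonic anhydrase gene cahz (-0.82), the anion exchanger gene slc4a1a (-0.69) and the membrane skeleton gene epb41b (-0.65). No member passed over all probes, and 10 passed when adjusted over the list alone.

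Genes of MHC class I presentation, which show peptides of cell proteins to T cells, rose as a group in mutant kidney, with 14 of 14 above 0 (12 in both replicates) and a median of 0.32 (0.33 and 0.34; adjusted p = 2.50e-10, and adjusted p = 0.4999 with an estimated correlation). Examples are mhc1zba (0.53) and mhc1uba (0.48), which encode class I chains, and the immunoproteasome genes psmb12 (0.43) and psmb9a (0.42). Interferon response genes rose too, with 15 of 16 above 0 and a median of 0.23 (0.30 and 0.18; adjusted p = 4.55e-09, and adjusted p = 0.357 with an estimated correlation), among them the regulators irf1b (0.80), socs1a (0.48) and irf7 (0.46) and the GTPase gene gbp1 (0.46). Adjusted over the list alone, 1 interferon gene and 0 class I genes passed. Outside the lists, the interferon-inducible genes ifi27.2 and ifi27.1 had ratios of 1.70 (SE 0.24; 1.40 and 1.99), or 3.24-fold higher, and 0.83 (0.82 and 0.83).

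Plasma protein genes made by hepatocytes fell as a group in mutant kidney, with 22 of 29 below 0 and a median of -0.34 (-0.40 and -0.16; adjusted p = 1.01e-04, and adjusted p = 0.752 with an estimated correlation). The coagulation list had 12 of 12 genes below 0 and a median of -0.39 (-0.60 and -0.22; adjusted p = 2.49e-04, and adjusted p = 0.752 with an estimated correlation). The acute phase list, which shares 7 of its 12 genes with other lists, had 8 of 9 below 0 and a median of -0.96 (-0.39 and -0.71; adjusted p = 2.49e-04, and adjusted p = 0.357 with an estimated correlation). Without kidney replicate 1 the hepatocyte call ended (adjusted p = 0.184), and so did that of coagulation (0.306). The lowest members of these lists were lower in replicate 1 than in replicate 2: in the hepatocyte list the transferrin gene tfa -2.55 (-3.45 and -1.64), the antiprotease gene serpina1 -2.18 (-3.48 and -0.88), the liver fatty acid-binding gene fabp10a -1.95 (-3.15 and -0.74), and in the coagulation and acute phase lists the fibrinogen gene fgg -1.82 (-2.93 and -0.71). No member of these 3 lists passed, over all probes or adjusted over the list alone.

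Cell cycle genes and neutrophil genes fell by smaller amounts in mutant kidney. Of the cell cycle genes 25 of 35 were below 0, with a median of -0.05 (0.03 and -0.15; adjusted p = 7.33e-04, and adjusted p = 0.752 with an estimated correlation), including ccnb1 (-0.24), kif11 (-0.23), birc5a (-0.23) and cdk1 (-0.23). Of the neutrophil genes 17 of 19 were below 0, with a median of -0.11 (0.13 and -0.38; adjusted p = 0.0289, and adjusted p = 0.752 with an estimated correlation), including the transcription factor genes cebpb (-0.51) and cebpa (-0.25), icn (-0.26) and the carboxypeptidase gene cpa5 (-0.24). Both lists turned to higher without kidney replicate 2, with adjusted p = 0.694 for cell cycle and 0.0684 for neutrophil. The neutrophil call also ended after scaling between arrays (0.136), with only the mutant in Cy3 (0.863) and without genes of other lists (0.0662). Adjusted over the list alone, 0 cell cycle and 0 neutrophil genes passed, where 3 and 0 had an unadjusted p under 0.05.

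Among the other named genes of the kidney, the highest ratios were those of gpx4b, a glutathione peroxidase gene, at 1.16 (SE 0.25; 1.22 and 1.09), cd9r at 0.88 (SE 0.17; 1.04 and 0.72), and agr1, an anterior gradient gene of secretory cells, at 0.85 (SE 0.06; 0.87 and 0.84). All were above 0 in the intestine replicates too, with 0.45 and 1.39 for gpx4b, 0.71 and 1.22 for cd9r, and 0.37 and 0.32 for agr1. Lower values of 0.80 to 0.45 in kidney were those of tfcp2l1, tomm20a, klhl24b, fabp7b and the antiviral GTPase gene mxe (0.45). The lowest was vg1, described as vitellogenin 1, an egg yolk precursor, at -2.55 (SE 1.93; -0.38 and -4.73). The keratin gene krt5 had -1.49 (-0.62 and -2.36), gadd45ga -1.39 (-0.68 and -2.095), pnp4b -1.44, the urate oxidase gene uox -1.35, ambp -1.34, the fibrinogen gene fgb -1.32 and leg1.2 -1.24. None of these passed the test.

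No probe passed in kidney with limma: 0 of 10482 probes had adjusted p under 0.05 (lowest 0.609), with 300 at unadjusted p under 0.05 (93 higher and 207 lower), where chance alone gives 524. That count was 445 with the scan batch as a block and 808 without kidney replicate 1. The main fit has no term for the replicate number, although deviations from the tissue mean correlated at 0.434 between tissues. What samples of the same number share therefore adds to its spread. A count under chance, here and below, thus does not show that genes were unchanged. With arrays kept apart and the replicate as a random block, limma called 21 probes (7 higher and 14 lower), and 14 (6 and 8) with a dye term. Of 20 lists tested, 8 were called (2 up and 6 down), 10 with the scan batch as a block, and 0 with an estimated correlation or with fry (lowest adjusted p = 0.357 and 0.0858).

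The remaining kidney lists were not called. The enterocyte list had 9 of 11 genes below 0 (adjusted p = 0.0980) and the stress and immediate early list 17 of 25 (adjusted p = 0.0980), and with the scan batch as a block these were called, at adjusted p = 0.0182 and 0.0197. With an estimated correlation adjusted p was 0.772 and 0.752. The T cell list had 6 of 7 genes below 0 (1 in both replicates) and a median of -0.13 (-0.09 and 0.06 by replicate, adjusted p = 0.340). Adjusted p was 0.156 for complement, 0.312 for MHC class II, 0.496 for muscle, 0.863 for ribosomal protein genes and 0.863 for inflammatory genes. It was 0.808 for exocrine pancreas (replicate medians -0.74 and 0.84), and 0.997 for macrophage (0.60 and -0.45), nephron, and cytotoxic and NK-like genes. Of the latter, nitr3a, an immune-type receptor gene, was at least 1.16-fold lower, since mutant RNA was not well above background. Of these lists, no member passed when adjusted over the list alone. Median, mean and test differed in sign for cytotoxic (0.03, 0.16, down), exocrine pancreas (0.03, -0.05, down), macrophage (0.06, 0.05, down), inflammatory (0.01, -0.02, up) and nephron genes (-0.01, 0.03, up). Too few genes were tested of the B cell list (3, of which 1 passed when adjusted over the list alone), recombination (2), thrombocyte (4, all below 0, median -0.14), secretory gut (3, of which agr1 passed when adjusted over the list alone) and vitellogenin lists (1).

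The second comparison asks the same of the intestine. The chaperone genes hsp70 and hsp70.3 had the highest ratios among the named genes of mutant intestine, at 2.34 (SE 0.45; 1.54 and 3.14), or 5.06-fold higher, and 2.32 (SE 0.47; 1.47 and 3.18). The stress list as a whole was not called there (camera adjusted p = 0.439). Interferon response genes rose as a group, with 11 of 13 above 0 and a median of 0.19 (0.10 and 0.21; adjusted p = 5.63e-04, and adjusted p = 0.482 with an estimated correlation), among them irf7 (0.59), mxe (0.48), irf1b (0.44) and gbp1 (0.43). MHC class I genes rose with 12 of 14 above 0 and a median of 0.15 (-0.01 and 0.22; adjusted p = 0.00173, and adjusted p = 0.482 with an estimated correlation), including mhc1zba (0.46), mhc1uba (0.39), b2m (0.26) and psme2 (0.24). Without intestine replicate 2 the class I list turned to lower (adjusted p = 0.651). For the single genes hsp70 and hsp70.3 adjusted p was 0.857, and 0.0301 with arrays kept apart and the replicate as a random block, a call that was lost with a dye term (0.0733).

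Macrophage genes rose as a group in mutant intestine, with 15 of 16 above 0 and a median of 0.33 (0.61 and 0.06; adjusted p = 0.00173, and adjusted p = 0.589 with an estimated correlation). The highest were mfap4.1 at 1.40 (2.76 and 0.05), the granulin gene grna.2 at 1.38 (2.36 and 0.40), the lysozyme gene lygl1 at 0.95 and the complement gene c1qc at 0.84, and the call ended without intestine replicate 1 (adjusted p = 0.814). Complement genes rose with 10 of 10 above 0 and a median of 0.71 (0.12 and 0.74; adjusted p = 3.31e-05, and adjusted p = 0.482 with an estimated correlation), including cfb at 1.31 (0.49 and 2.12), cfhl2 (0.80) and masp2 (0.77). Adjusted over the list alone, 0 genes of the interferon, class I, macrophage and complement lists passed.

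Genes of liver and pancreas rose as groups in mutant intestine, mostly through replicate 2. The hepatocyte list had 30 of 32 genes above 0 and a median of 0.49 (0.03 and 0.94; adjusted p = 1.52e-08, and adjusted p = 0.482 with an estimated correlation), including igfbp1a (1.27), serpina7 (1.25), pah (1.04) and itih2 (0.86). The coagulation list had 13 of 14 above 0 and a median of 0.53 (0.07 and 1.02; adjusted p = 3.31e-05, and adjusted p = 0.482 with an estimated correlation), including the factor V gene f5 (1.08) and the antithrombin gene serpinc1 (1.03). Exocrine pancreas genes, for digestive enzymes, had 10 of 10 above 0 and a median of 0.53 (0.11 and 1.01; adjusted p = 2.12e-04, and adjusted p = 0.482 with an estimated correlation), including cel.1 (0.78), ela2l (0.66), cpa5 (0.61) and amy2a (0.59, with mutant RNA saturated on 2 arrays and heterozygote RNA on 1). Without intestine replicate 2 adjusted p was 0.295 for hepatocyte, 0.467 for coagulation and 0.239 for exocrine pancreas genes. A haptoglobin-like transcript, chosen after its value was seen, had 1.27 (SE 0.11; 1.46 and 1.07; adjusted p = 0.857, and 0.0242 with the replicate as a random block) in intestine and -0.16 in kidney.

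Ribosomal protein genes fell as a group in mutant intestine, with 61 of 61 below 0 but 23 in both replicates, and a median of -0.25 (0.02 and -0.49; adjusted p = 2.33e-14, and adjusted p = 0.482 with an estimated correlation). Examples are rps20 (-0.55, with heterozygote RNA saturated on 1 array), rpl37 (-0.44) and rpl10a (-0.43), and without intestine replicate 2 the list turned to higher (adjusted p = 0.239). Cell cycle genes rose with 15 of 16 above 0 and a median of 0.09 (0.07 and 0.12; adjusted p = 0.00173, and adjusted p = 0.482 with an estimated correlation), including the replication genes pcna (0.24) and rpa2 (0.23). Their call ended without intestine replicate 1 (adjusted p = 0.0546), without replicate 2 (0.131), with no filter on dim probes (0.0565) and with only the mutant in Cy3 (0.254). Secretory gut genes rose with 5 of 5 above 0 and a median of 0.11 (0.09 and 0.06; adjusted p = 0.0305, and adjusted p = 0.482 with an estimated correlation), including agr1 (0.35, the 1 gene that passed when adjusted over the list alone), the somatostatin gene sst1.1 (0.32) and the glucagon gene gcga (0.11). Adjusted p was 0.0641 with the scan batch as a block, 0.0649 after scaling between arrays, 0.0605 with the replicate as a random block, 0.254 with only the mutant in Cy3 and 0.464 without intestine replicate 1. Muscle genes rose with 7 of 8 above 0 and a median of 0.11 (0.03 and 0.16; adjusted p = 0.0395, and adjusted p = 0.482 with an estimated correlation), including tnnt3b (0.41) and mylpfa (0.37), while the actin gene acta2 lay below 0 (-0.36 to -0.09 over the alternative settings). The muscle call ended without any 1 replicate, with only the mutant in Cy5 (adjusted p = 0.2498) and with the replicates of intestine alone (0.0732). No other member of the lists called in intestine passed when adjusted over the list alone.

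Other high ratios in intestine were those of the amylase gene amy2al2 at 1.32 (0.67 and 1.97), tdo2b at 1.23, agt at 1.098, krt5 at 1.00 and the fibrinogen gene fga at 0.97. The lowest was vg1 at -3.11 (SE 1.93; -0.08 and -6.14), where heterozygote RNA was saturated on 2 of 4 arrays, those of replicate 2, so that the size of the replicate 2 value may be understated. It was followed by the oestrogen receptor gene esr1 at -1.48 (-0.11 and -2.85), gadd45ba at -1.36 (-0.40 and -2.33), zbtb16a at -1.27 and eif4ebp3 at -1.25, whose other probe lay at 0.27. Then came sat2a.2 at -1.20 (-2.23 and -0.18), the bile acid synthesis gene hsd3b7 at -1.20, the bile acid transporter gene slc10a2 at -1.10 (-0.40 and -1.81), the fatty acid desaturase gene fads2 at -1.10 (-0.57 and -1.62), mycb at -0.96, gadd45ga at -0.80 and the ribosomal gene rps27.2 at -0.78. None of these passed the test.

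No probe passed in intestine with limma: 0 of 8086 (lowest adjusted p = 0.857), with 348 at unadjusted p under 0.05 (171 higher and 177 lower), where chance alone gives 404. That count rose to 597 with the scan batch as a block and to 1156 without intestine replicate 1. The random block fit called 18 probes (14 higher and 4 lower), and 3 with a dye term. Of 19 lists tested, 11 were called (10 up and 1 down), 5 without intestine replicate 2, and 0 with an estimated correlation or with fry (lowest adjusted p = 0.482 and 0.515).

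Of the other intestine lists, the acute phase list had 7 of 10 genes above 0 (adjusted p = 0.0690, and 0.0280 with the scan batch as a block), and the erythroid list 10 of 14 below 0 (adjusted p = 0.0979). Adjusted p was 0.620 for neutrophil, 0.580 for enterocyte, 0.546 for nephron, and 0.439 for each of MHC class II, inflammatory and stress genes. No member of these lists passed when adjusted over the list alone. Median, mean and test differed in sign for neutrophil (-0.01, 0.01, down) and inflammatory genes (-0.01, 0.02, up). Too few genes were tested of the T cell list (3, with trac at -0.23, lck at -0.21 and runx3 at -0.14), cytotoxic (2), thrombocyte (2), B cell (1), vitellogenin (1, esr1) and recombination lists (0). The IgM probes had ratios of -0.47 (-0.28 and -0.65, not tested) and -0.80 (-0.39 and -1.22, adjusted p = 0.857).

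**Figure D1:**
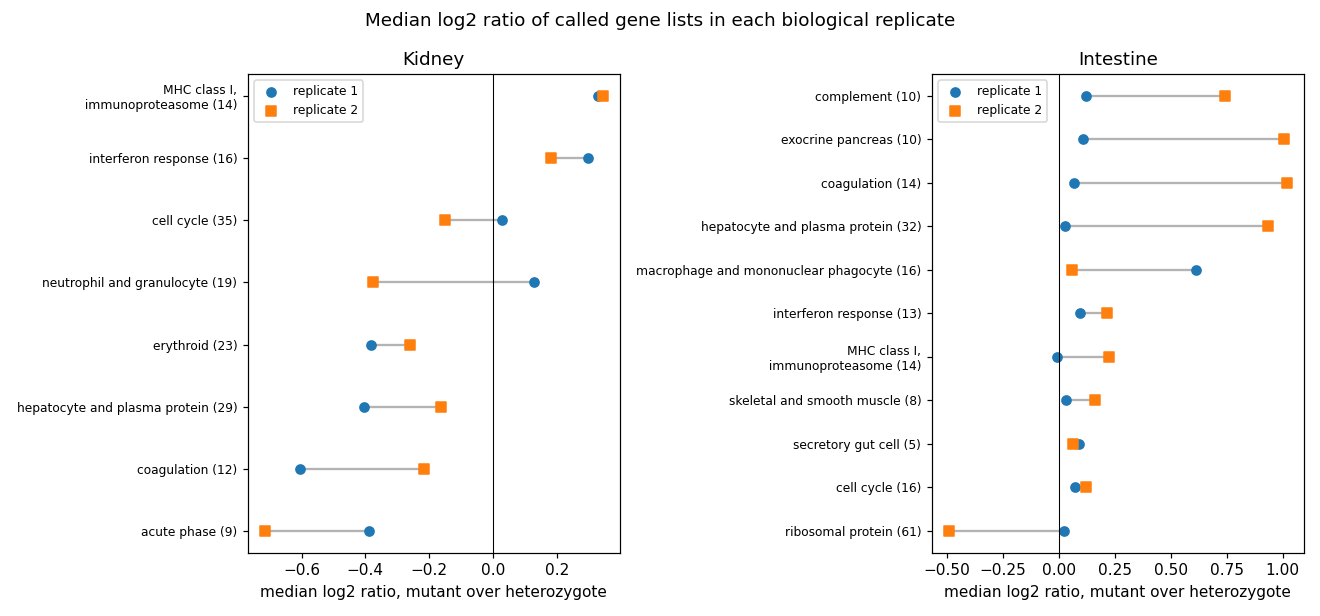
Median log2 ratio of mutant over heterozygote for each called gene list in kidney and in intestine, 1 point per replicate (circle replicate 1, square replicate 2), with the number of tested genes in brackets. Erythroid genes in kidney lie at -0.38 and -0.26, and ribosomal protein genes in intestine at 0.02 and -0.49.

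**Figure D2:**
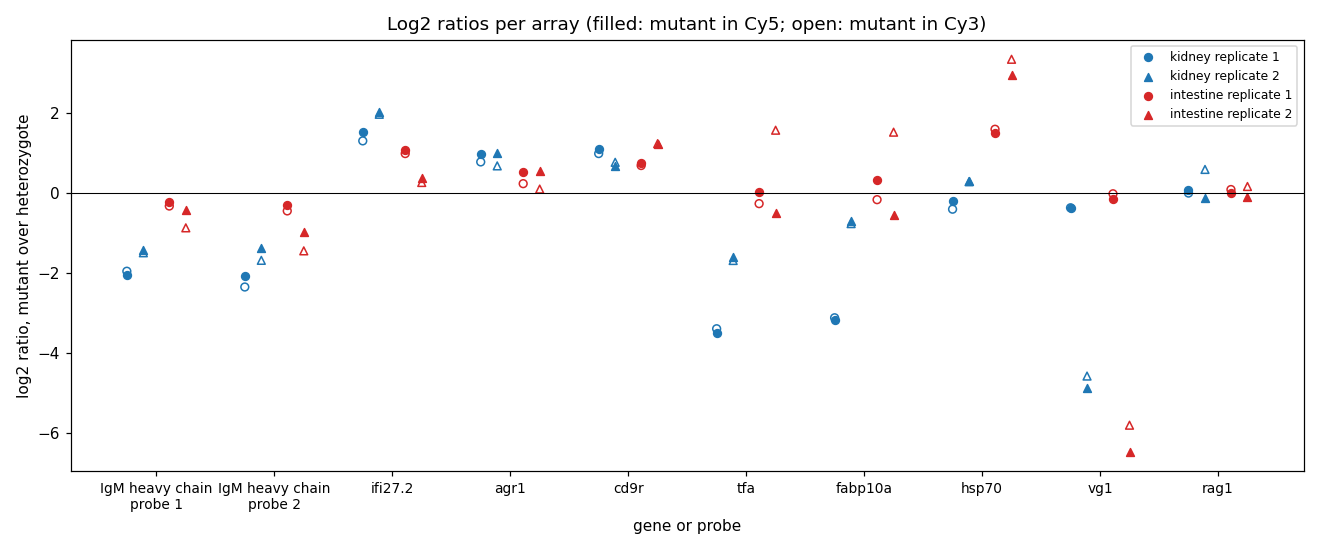
Log2 ratio of mutant over heterozygote on each array for 10 probes (blue kidney, red intestine; circle replicate 1, triangle replicate 2; filled with the mutant in Cy5, open with the mutant in Cy3). Both IgM probes lie below -1 on all 4 kidney arrays, and rag1 lies near 0 on most arrays.

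The third comparison asks whether the effect of the genotype differs between the tissues, as kidney minus intestine. By the size of the median among the tested lists, liver-type genes differed most: the hepatocyte list had 28 of 28 genes lower in the difference and a median of -0.94 (adjusted p = 3.19e-18), coagulation 12 of 12 and -0.87 (3.79e-09), complement 7 of 7 and -0.78 (1.70e-05), and acute phase 8 of 9 and -0.96 (3.43e-05). For each of these, adjusted p = 0.407 with an estimated correlation. The named genes behind them were fgg at -2.73 (SE 1.01), tfa at -2.74 and serpina1 at -2.60, where tfa was saturated in a channel on 3 intestine arrays and serpina1 on 2, so that the size of these differences is uncertain. Ribosomal protein genes were higher in the difference, with 61 of 61 genes and a median of 0.25 (adjusted p = 1.27e-12, and adjusted p = 0.499 with an estimated correlation), and so were MHC class I genes, with 12 of 14 and 0.12 (0.00961, and adjusted p = 0.499 with an estimated correlation).

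Lists lower in the difference also included erythroid genes (10 of 14, median -0.10, adjusted p = 0.00305), stress genes (17 of 23, -0.16, 0.00278) and muscle genes (8 of 8, -0.29, 0.00305), each with adjusted p = 0.407 with an estimated correlation. Cell cycle (16 of 16, -0.13, 0.00152) and exocrine pancreas genes (7 of 7, -0.51, 0.00968) had adjusted p = 0.499 with an estimated correlation. Macrophage (14 of 16, -0.26, 0.00638) and enterocyte genes (8 of 11, -0.15, 0.0443) had adjusted p = 0.556 with an estimated correlation. Leaving out 1 replicate turned or ended the call of 9 of the 13 lists, and only the hepatocyte, coagulation, complement and acute phase lists were called without each replicate in turn. Without kidney replicate 1, adjusted p was 0.218 for erythroid, 0.218 for MHC class I, 0.625 for enterocyte and 0.2997 for exocrine pancreas genes, the latter turned to higher. Without kidney replicate 2 it was 0.531 for cell cycle, 0.204 for stress, 0.832 for muscle and 0.204 for macrophage genes, the latter turned to higher. Without intestine replicate 1 it was 0.877 for macrophage, 0.237 for erythroid, 0.237 for stress and 0.877 for MHC class I genes, the latter turned to lower. Without intestine replicate 2 it was 0.212 for exocrine pancreas and 0.0697 for cell cycle genes, and the enterocyte (0.237) and ribosomal lists (0.391) turned. The erythroid call also ended with the value table (0.0981), with offset 0 (0.0619) and with the processed signals (0.215), the muscle call with no filter on dim probes (0.0611), the MHC class I call without genes of other lists (0.170), and the exocrine pancreas call in 3 other settings (0.107 to 0.189). The enterocyte call was kept in 11 of 22 settings. Not called were interferon (0.0577), neutrophil (0.0999, and 0.0165 with the replicate number as a block), inflammatory (0.285), nephron (0.756, with a median of 0.02, a mean of 0.03 and a test downward) and MHC class II genes (0.940).

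Named genes with the highest difference were sat2a.2 (1.81, SE 1.06), esr1 (1.54), egln3, a prolyl hydroxylase gene (1.15), slc10a2 (1.14), ifi27.2 (1.02) and zbtb16a (0.99, and -0.12 without intestine replicate 2). The others with the lowest were krt5 (-2.49), hsp70 (-2.34) and hsp70.3 (-2.32). No probe passed with limma: 0 of 7719 (lowest adjusted p = 1.00), with 126 at unadjusted p under 0.05 (40 higher and 86 lower), where chance alone gives 386, and 0 in the random block fits and with the value table. With the replicate number as a block, 263 probes had an unadjusted limma p under 0.05. Of 18 lists 13 were called (2 up and 11 down), 14 with the replicate number as a block, and 0 with an estimated correlation or with fry (lowest adjusted p = 0.407 and 0.717). Adjusted over the list alone, 1 gene passed, in the secretory gut list, of which 3 genes were tested here, too few for a test of the list. In both tissues, 20 of 7719 probes were higher and 25 lower at unadjusted limma p under 0.05. The separate counts would give 1.28 and 2.58 for independent tissues. The tissues share 1 spread estimate per probe in the fit, so they are not independent. Genes higher in both included agr1, cd9r, gpx4b and ifi27.1, and genes lower in both fads2, sdr16c5b and slc39a13.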

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

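All 8 tests of explanations in this part, and the tests of lists in the tissue difference, were chosen after the results they concern had been seen.

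Liver-type genes had lower ratios in kidney than in intestine: the tissue difference of the hepatocyte list had adjusted p = 3.19e-18, of coagulation 3.79e-09, of complement 1.70e-05 and of acute phase 3.43e-05, and each had adjusted p = 0.407 with an estimated correlation. Within the tissues, complement was not called in kidney (0.156) and acute phase was not called in intestine (0.0690). In kidney replicate 1, 27 of 29 hepatocyte genes lay below 0, and the 5 brightest had a median of -1.303 against -0.368 for the others (-0.609 against -0.135 in replicate 2), in the direction that different amounts of liver tissue in the dissected kidney samples would give. With offset 0, which draws the ratios of dim probes less toward 0, the medians in replicate 1 were -1.34 and -0.748, within the quartiles of the others (-1.751 and -0.189), so the amount of liver tissue cannot be told apart from other causes. A genotype effect shared by both kidney replicates stays open too, since the hepatocyte median in replicate 2 was -0.16 against -0.40 in replicate 1. In intestine replicate 2, 31 of 32 lay above 0, and the 5 brightest had a median of 0.52 against 1.04 for the others. Of these 5, 4 were saturated in a channel on 2 or 3 of all 8 arrays (rbp4 0.09, apoc1 0.87, fabp10a 0.47 and tfa 0.52 in intestine replicate 2). Only for tfa are these known to be intestine arrays (3 arrays). The amount of liver tissue in the intestine samples cannot be told apart from other causes. Of the list's 36 genes on the array 4 are also in other lists, and 29 and 32 were expressed well enough for a test in kidney and intestine.

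Erythroid genes were lower and MHC class I genes higher in kidney (adjusted p = 0.357 and 0.4999 with an estimated correlation), and the tissue difference had adjusted p = 0.00305 and 0.00961, which became 0.407 and 0.499 with an estimated correlation, 0.218 and 0.218 without kidney replicate 1 and 0.237 and 0.877 without intestine replicate 1. Genes held by other lists do not account for the interferon call in kidney. With the 12 genes left, camera at the preset correlation gave adjusted p = 2.47e-06. The call of the whole list was lost with an estimated correlation (adjusted p = 0.357). That correlation was -0.03, so correlated genes do not explain the loss, and that test rests on 2 residual degrees of freedom. A lower share of lymphocytes would raise markers of other cell types alike, and the erythroid median lay below that of nephron genes (a difference of -0.32; -0.36 and -0.26 by replicate), but in replicate 2 their quartiles overlapped, so this cannot be told apart from other causes. Of 23 erythroid genes, 20 lay below 0 in replicate 1 and 16 in replicate 2 (69.6%). A lower share of red blood cells cannot be told apart from lower erythroid transcription by such counts, since both would lower these genes. An effect of the rag1 genotype on these genes stays open, as untested.

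The vg1 ratio was far below 0 in replicate 2 of both tissues (-4.73 in kidney and -6.14 in intestine, where heterozygote RNA was saturated on both arrays, so that its size may be understated), against -0.38 and -0.08 in replicate 1. A lower amount of liver in the mutant sample, the organ that makes yolk protein, would lower other liver genes too, but in intestine replicate 2 their median was 0.94 (quartiles 0.74 and 1.25), which argues against it there. In kidney replicate 2 the hepatocyte median was -0.16, with 20 of 29 genes below 0, so in kidney a lower amount of liver cannot be told apart from other causes. A different sex of the fish in replicate 2 cannot be told apart from other causes: the sex is not given in the sources used here, and only 1 gene of the vitellogenin and oocyte list, esr1, was tested in intestine, with -2.85 in replicate 2 there but 0.10 in kidney replicate 2. An effect of the genotype on vg1 stays open, as untested, with the 2 replicates far apart.

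Further lists differed between the tissues, by the test of the difference: ribosomal protein (adjusted p = 1.27e-12), cell cycle (0.00152), stress (0.00278), muscle (0.00305), macrophage (0.00638), exocrine pancreas (0.00968) and enterocyte (0.0443). With an estimated correlation their adjusted p was 0.407 to 0.556, and each of these 7 calls was lost or turned without some replicate. An array apart from the other arrays of its tissue was found in 3 of 95 sets of 4 arrays. A chance rate of about 1 in 20 holds for independent values, which arrays of a dye-exchange pair are not. Cy5 background, here in whole numbers, was 57 on kidney replicate 1 with the mutant in Cy5 (56 on the others) and 55 on intestine replicate 1 with the mutant in Cy3 (56 on the others). The kidney gpx4b ratio was 0.99 on replicate 2 with the mutant in Cy5 (1.199 to 1.239 on the others).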

How the results depend on the processing

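The alternatives for lists without shared genes and for the lists of the tissue difference were chosen after seeing the data. With limma 0 probes passed in every setting but those that kept arrays apart: with the replicate as a random block the kidney calls were 21 and the intestine calls 18, and with a dye term 14 and 3. In these fits arrays of a pair add degrees of freedom, and SEs change too (from 0.45 to 0.30 for hsp70 in intestine without a dye term). Which of these made the calls was not tested. With a replicate block, which is also the scan batch block, the tissue difference had 0 calls (263 at unadjusted p under 0.05) and 14 lists. Deviations from the tissue mean correlated at 0.434 between samples that share a replicate number and a scan batch. With an estimated correlation 0 lists were called in kidney, 0 in intestine and 0 in the difference, and likewise 0, 0 and 0 with fry. Lists without genes of another list gave 6, 11 and 10 calls. The rag1 level check in kidney moved to 0.35 with offset 0, 0.36 with the scanner software's processed signals, -0.037 with only the mutant in Cy5 and 0.29 with only the mutant in Cy3. In intestine, where mutant RNA was not well above background on any array, the ratio of the measured intensities moved from 0.0335 to 0.0166 with no background subtraction, 0.221 with offset 0, -0.107 with the processed signals, -0.052 with only the mutant in Cy5 and 0.119 with only the mutant in Cy3. The nephrosin ratio in kidney ran from -5.33 with the processed signals to -2.645 with only the mutant in Cy3, a setting that left 1 array of replicate 1. With only the mutant in Cy5, syk in kidney was -0.033 and the haptoglobin-like transcript in kidney 0.012, and with only the mutant in Cy3, sstr5 in intestine was -0.076. The cause was not tested.

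Leaving out 1 replicate, with the lone sample assumed to vary like the other tissue's, gave 8 to 11 lists called in kidney, 5 to 10 in intestine and 9 to 11 in the difference. Adjusted p of lists that turned ran from 2.82e-04 to 0.0684 (kidney neutrophil), 3.54e-05 to 0.694 (kidney cell cycle), 1.65e-04 to 0.651 (intestine MHC class I), 6.19e-27 to 0.239 (intestine ribosomal), and in the difference 1.60e-08 to 0.2997 (exocrine pancreas), 7.28e-07 to 0.877 (macrophage), 5.05e-08 to 0.877 (MHC class I), 1.33e-04 to 0.625 (enterocyte) and 7.34e-28 to 0.391 (ribosomal). Log2 ratios of genes that turned ran, in kidney, from -0.59 to 0.056 for lck, -0.70 to 0.21 for tagapb, -0.66 to 0.36 for trac, -1.097 to 0.083 for cebpb, -0.65 to 0.13 for icn, -0.74 to 0.26 for cpa5, -0.042 to 0.95 for gbp1 and -0.68 to 0.24 for the T cell receptor beta transcript. In intestine they ran from -0.54 to 0.069 for trac, -0.061 to 2.22 for f5, -0.040 to 2.095 for serpinc1, -0.25 to 1.98 for itih2, -0.01 to 0.94 for mhc1zba, -0.27 to 1.04 for mhc1uba, -0.0001 to 0.51 for b2m, -0.038 to 0.68 for sst1.1, -0.01 to 0.43 for actc1b and -0.94 to 0.062 for rpl37, and in the difference from -0.12 to 2.09 for zbtb16a. By construction these fits rest on fewer replicates.

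Over all settings, the called lists kept their call in 621 cases, lost it in 116 and turned in 9. In kidney the erythroid, interferon, MHC class I and acute phase lists kept theirs in the other settings that gave them a value (20 for acute phase, which had none without genes of another list, and 21 for the others), all but the estimated correlation and fry, with highest adjusted p = 0.00136, 0.00218, 0.00218 and 0.0236. The value table was not run for single tissues, because it is centred by probe. Signal over background, lowest in Cy5, limits what dim probes such as rag1 can show.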

Other observations

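The single genes in this part were chosen after their values were seen, with adjusted p from limma with arrays kept apart and the replicate as a random block, and none passed with the pairs averaged. The random block fit counts arrays of a pair toward the degrees of freedom, although each tissue had 2 biological replicates, so its adjusted p can be too low.

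In intestine, single probes of some chaperone genes other than hsp70 had high ratios: a probe of hsp90ab1 had 1.86 (1.70 and 2.03 in replicates 1 and 2; adjusted p = 0.00112, and 0.00914 with a dye term) and a probe of hsp90aa1.1 had 0.78 (0.70 and 0.86; adjusted p = 0.0242, and 0.0733 with a dye term). The brightest probes of these genes differed, at 0.09 for hsp90ab1 and 0.19 for hsp90aa1.1. Other chaperone genes lay nearer 0, with -0.59 and 0.05 for hspa5, 0.04 and 0.15 for dnajb1a and 0.27 and 0.05 for hspb1, and the stress list was not called in intestine. The desaturase gene fads2 was low in both tissues, at -1.18 and -1.28 in the kidney replicates and -0.57 and -1.62 in the intestine replicates at its brightest probe, and 1 other probe had adjusted p = 0.0436 in intestine, and 0.0935 with a dye term.

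In kidney, low ratios outside the lists were those of sdr16c5b at -0.91 (-0.86 and -0.96; adjusted p = 0.00244), the zinc transporter gene slc39a13 at -0.96 (-0.926 and -1.002; 0.00545), the amino acid transporter gene slc38a4 at -1.18 (-1.13 and -1.23; 0.0152) and the chemokine receptor gene cxcr4a at -0.91 (-0.67 and -1.14; 0.0180). The cathepsin gene ctss1 had 0.79 (0.63 and 0.96; 0.0160) at 1 probe, but 0.61 and -0.40 at its brightest probe. With a dye term the call of cxcr4a was lost (adjusted p = 0.0552) and those of the others were kept. With the pairs averaged, sdr16c5b and slc39a13 were lower in intestine too, at unadjusted limma p under 0.05 in both tissues.

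Some genes had different values in the replicates of both tissues. The NF-kappa-B inhibitor gene nfkbiab had -1.49 in kidney and -1.33 in intestine in replicate 2, against 0.19 and 0.81 in replicate 1. The antiproliferative gene btg2 had -1.34 and -1.02 in replicate 2 against -0.35 and 0.25. Macrophage genes had medians of 0.60 and 0.61 in replicate 1 against -0.45 and 0.06 in replicate 2.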
